A study of Homo sapiens with 26 samples.

How the data were processed

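Total RNA of HCT116 cells, grown in McCoy medium, was extracted with Trizol, amplified with an Illumina TotalPrep kit and labelled with streptavidin-Cy3, per the labels' protocols. Cells labelled p53 wild type or p53 knockout were untreated or exposed to 2 or 20 nM leptomycin B for 16 h, per the labels. One array was hybridised per sample, 26 in all. The deposited table holds an intensity per probe and array on a linear scale, which the authors produced with BeadStudio, per the submitters' processing notes. The version, the background correction and the normalization method are not given in the sources used here. The values show that background had been subtracted, since 20.4% were below 0, and that arrays had been brought to a common distribution, since their percentiles lay within 1.15% of the mean over arrays. Values ranged from -27.2 to 27669 with a median of 10.2. No array has a detection p in the table used here, and the number of arrays sets the precision.

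Probes were named from the platform annotation supplied with the reference tables. Of 22177 probes, 21101 had 1 gene symbol, none had several and 1076 had none and were not tested. Entrez identifiers matched the reference gene table for 20986 probes, and no symbol needed an update. The 21101 probes stand for 17283 genes. The probe with the highest mean intensity stood for its gene, which was a choice among several probes for 2216 of the genes tested. The transcript of the deleted gene was not analysed here, so it gives no check of the genotype labels.

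Arrays were grouped by the genotype, dose and replicate number in their labels. The slide identifiers in the labels split them into 7 slides in 2 series, the first with untreated replicates 4 to 6 and the 20 nM arrays, the second with untreated replicates 7 to 10 and the 2 nM arrays. Intensities under 10 were set to 10 and log2 values taken, so changes of dim genes are understated, as for 49.7% of values at or below 10. No further normalization was applied. Genes had to lie above the 40th percentile of the array on at least 3 arrays, which left 12833. A linear model with 8 cells (genotype, treatment and series) and 18 residual degrees of freedom was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with statmod 1.5.0 for random blocks and jsonlite 2.0.0 for the labels. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and an adjusted p under 0.05 counted as a call. Each response is treated minus untreated arrays of the same label and series. The genotype comparison of untreated cells is the mean of the differences of the 2 series, and the genotype and dose comparisons of responses are differences of responses, tested directly. Where all arrays of an arm lay at the floor of 10, folds are bounds, and where only some did, the fitted change is given and is understated. Values set to 10 do not vary, so the SE and p of such genes may be too small.

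Gene sets were tested with camera with a preset correlation of 0.01, and again with an estimated correlation. With the latter, of the calls in the 4 responses, those of histone genes in all 4 held, as did G2/M and G1/S genes, DNA repair genes and XPO1 markers in WT-labelled cells at 20 nM and KO-labelled cells at 2 nM. The directional test fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes, was an alternative. The 29 lists were p53 targets, nuclear export and import machinery, XPO1 inhibitor marker genes, G2/M genes, G1/S and DNA replication genes, histone genes, cholesterol synthesis, ATF4 and unfolded protein response, heat shock, NF-kB targets, NRF2 targets, immediate early genes, FOXO targets, interferon response, ribosome biogenesis, cytosolic ribosomal proteins, BCL2 family and caspases, intestinal epithelial genes, TFEB and lysosome genes, TGF-beta targets, Wnt targets, YAP targets, hypoxia, oxidative phosphorylation, DNA repair, splicing and mRNA export, housekeeping genes, fibroblast markers, and blood and endothelial cell markers. Lists overlap: 10 p53 targets and 9 BCL2 family and caspase genes stand in another list too. Of 11 fibroblast and 16 blood and endothelial markers, 4 and 7 were tested.

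The genes named are CDKN1A, MDM2 and XPO1 in every comparison, the 8 called genes with the largest rise and the 8 with the largest fall among those whose arms do not overlap (the 6 largest each way, without that condition, for differences between responses), and up to 4 called members of each list described. The lists described are those with a camera adjusted p under 0.05, and always the p53 targets, the export and import machinery and the other cell type markers. The groups, tests, gene lists, naming rule and most of the other settings tried were fixed before the data were examined. A pass over the data with the same model preceded the final run and changed no setting.

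Whether replicate numbers pair arrays of the 2 labels was checked by the correlation of their deviations from the cell means. It was 0.33 to 0.81 over the 7 untreated pairs, but arrays 4 and 10 pull the cell means, and among the other untreated arrays alone it was 0.006 to 0.068. So the numbers pair arrays 4 and arrays 10 at most. It did not exceed 0.1 in most of the treated pairs, which were not treated as paired either. The pairing comes from the numbers in the labels and this check. The other settings fixed in this way were quantile normalization, median centring, floors of 1 and 50, an added offset of 50, no filter and a filter at the 60th percentile, all probes, slide series as an additive block or ignored, slide as a random block, replicate number as a block, a fit on only the arrays compared, an intensity trend with robust variances, array weights, and each array left out in turn. Further settings were chosen after seeing the data: leaving out untreated arrays 4 and 10, using them as the only controls, exchanging the genotype names of the second series, and centring over probes above 50.

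The model was tested on simulated data with 50 of 12833 genes changed at each of 4 sizes. For the WT response at 20 nM, 29 of 50 genes changed by 0.5 were recovered, 42 of 50 changed by 1 and 50 of 50 changed by 2 or by 4 on the log2 scale, with 8 unchanged genes called. For the 20 nM genotype difference the numbers were 14, 37, 48 and 50, with 9 unchanged genes called. For the WT dose difference they were 14, 37, 45 and 50, with 15 unchanged genes called. Of 100 random lists, 2 had a camera p under 0.05. Genes were simulated as independent of each other and without arrays that stand apart. So this does not test the preset correlation on lists of genes that vary together.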

Results

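HCT116 is a human colon carcinoma cell line whose parental cells carry functional p53, the transcription factor that halts the cell cycle and promotes apoptosis after stress. Total RNA of cells labelled p53 wild type (WT) or p53 knockout (KO) was hybridised to 26 one-colour Illumina expression arrays. Cells were untreated or had been exposed for 16 h to leptomycin B, a covalent inhibitor of the nuclear export receptor XPO1 (CRM1), at 2 or 20 nM. Each genotype label held 7 untreated arrays, 3 arrays at 20 nM and 3 arrays at 2 nM. The arrays came in 2 slide series. Series 1 held untreated replicates 4 to 6 and all 20 nM arrays, and series 2 held untreated replicates 7 to 10 and all 2 nM arrays. The number of arrays limits the precision of every value. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. All changes are given as log2 differences ± SE from the limma model, with Benjamini-Hochberg adjusted p-values over 12833 genes.

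The first comparison asked how untreated cells of the 2 genotype labels differed. CDKN1A, the p53-induced cyclin-dependent kinase inhibitor p21, fell by 2.27 ± 0.37 in KO-labelled against WT-labelled arrays of series 1 (n = 3 and 3, adjusted p = 3.2e-04) and was 2.61 ± 0.32 higher in KO-labelled arrays of series 2 (n = 4 and 4, adjusted p = 1.8e-05). CASP4, an inflammatory caspase, was at -5.27 ± 0.31 in series 1 and 4.32 ± 0.26 in series 2, where 3 of 4 WT-labelled arrays lay under the floor of 10, so that this size is understated. PROM1, which encodes the surface antigen CD133, was at least 28.2-fold lower in KO-labelled arrays of series 1 and at least 33.2-fold higher in those of series 2. NRIP1, a nuclear receptor corepressor, was at least 15.5-fold lower and then at least 20.1-fold higher. GDF15, a secreted p53-induced cytokine, was at -3.47 ± 0.51 in series 1. In the opposite sense, ZBED2 was at 3.12 ± 0.48 and -3.22 ± 0.41, and CAMK2D, a calcium-dependent kinase, at 2.27 ± 0.18 and -2.16 ± 0.16.

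Because the 2 series ran opposite ways, every genotype below is the genotype of the label. In series 1, 24 of 51 p53 targets were lower and none was higher in KO-labelled arrays (26 lower and 1 higher adjusted over the list alone; median -0.64, camera adjusted p = 2.2e-13, adjusted p = 0.256 with an estimated correlation). In series 2, 12 were higher and 1 was lower (15 and 1 adjusted over the list alone; median 0.23, adjusted p = 3.3e-04, adjusted p = 0.879 with an estimated correlation). Series 1 had 924 genes higher and 1016 lower in KO-labelled arrays, and series 2 had 567 higher and 627 lower. Of 668 genes called in both series, 667 had opposite signs, where 90.0 would be opposite if the lists were independent. Across all genes tested, which are not independent replicates, the 2 differences had r = -0.72 (Spearman's rho -0.55). These within-series comparisons share no arrays.

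The mean of the 2 series' differences, which was the planned comparison, held 40 genes, 12 higher and 28 lower in KO-labelled arrays, and 1417 genes at an unadjusted p under 0.05. NRDC, a metalloendopeptidase, was at -0.28 ± 0.05 (n = 7 and 7, adjusted p = 0.0119, and 0.0508 without KO-labelled replicate 6). CDKN1A was at 0.17 ± 0.25 (adjusted p = 0.95), MDM2, the p53-induced ubiquitin ligase of p53, at -0.04 ± 0.20, and XPO1 at -0.05 ± 0.10. The p53 targets had a median of -0.24 with 1 of 51 lower (13 lower adjusted over the list alone; camera adjusted p = 2.8e-10, adjusted p = 0.763 with an estimated correlation). Interferon response genes had a median of -0.18 with 1 of 28 lower (3 adjusted over the list alone; adjusted p = 1.7e-05, adjusted p = 0.763 with an estimated correlation). ATF4 and unfolded protein response genes, at -0.20, G2/M genes, at 0.07, and ribosome biogenesis genes, at 0.12, also passed camera without a called member (adjusted p = 1.1e-04, 0.00111 and 0.00111), and adjusted p was 0.763, 0.763 and 0.802 with an estimated correlation. These means join series that differ. Interferon response genes were at -0.51 in series 1 (10 lower, 14 over the list alone) and 0.07 in series 2 (4 higher, also over the list alone), and G2/M genes at 0.32 (12 higher, 18 over the list alone) and -0.17 (5 lower, also over the list alone). ATF4 genes were at -0.23 and -0.035 and ribosome biogenesis genes at 0.27 and -0.034. The nuclear export and import machinery was at 0.162 in series 1 (8 higher, 9 over the list alone; camera adjusted p = 0.00106, adjusted p = 0.461 with an estimated correlation) and -0.072 in series 2 (3 lower, also over the list alone; adjusted p = 0.0702). In the mean of the series, adjusted over these lists alone, 3 G2/M genes were higher and no member of the ATF4 or ribosome biogenesis lists passed. Neither the nuclear export and import machinery (median 0.04, no member called, 1 higher adjusted over the list alone, adjusted p = 0.0847) nor the markers of fibroblasts or of blood and endothelial cells passed.

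The count of this planned comparison depended on single arrays. Without untreated arrays 4 and 10 of both labels it was 3509, and leaving out 1 array gave 17 to 1477. It was 1477 without KO-labelled replicate 4, 580 without WT-labelled replicate 4, 491 without KO-labelled replicate 10, 73 without WT-labelled replicate 10 and 17 to 24 without WT-labelled replicate 5, 6, 7 or 8 or KO-labelled replicate 5, 6, 7, 8 or 9. The calls of the G2/M and ATF4 lists were lost without KO-labelled replicate 4 (adjusted p = 0.137 and 0.0928) or WT-labelled replicate 5 (0.0673 for both), that of the ATF4 list also without WT-labelled replicate 6 (0.076), and that of ribosome biogenesis without WT-labelled replicate 10 (0.282). The median of the p53 targets was -0.455 without WT-labelled replicate 4 and -0.16 without WT-labelled replicate 6, and that of the ATF4 list -0.347, -0.108 and -0.087 without WT-labelled replicates 4, 5 and 6. Interferon response genes were at -0.287 without KO-labelled replicate 10.

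**Figure D1:**
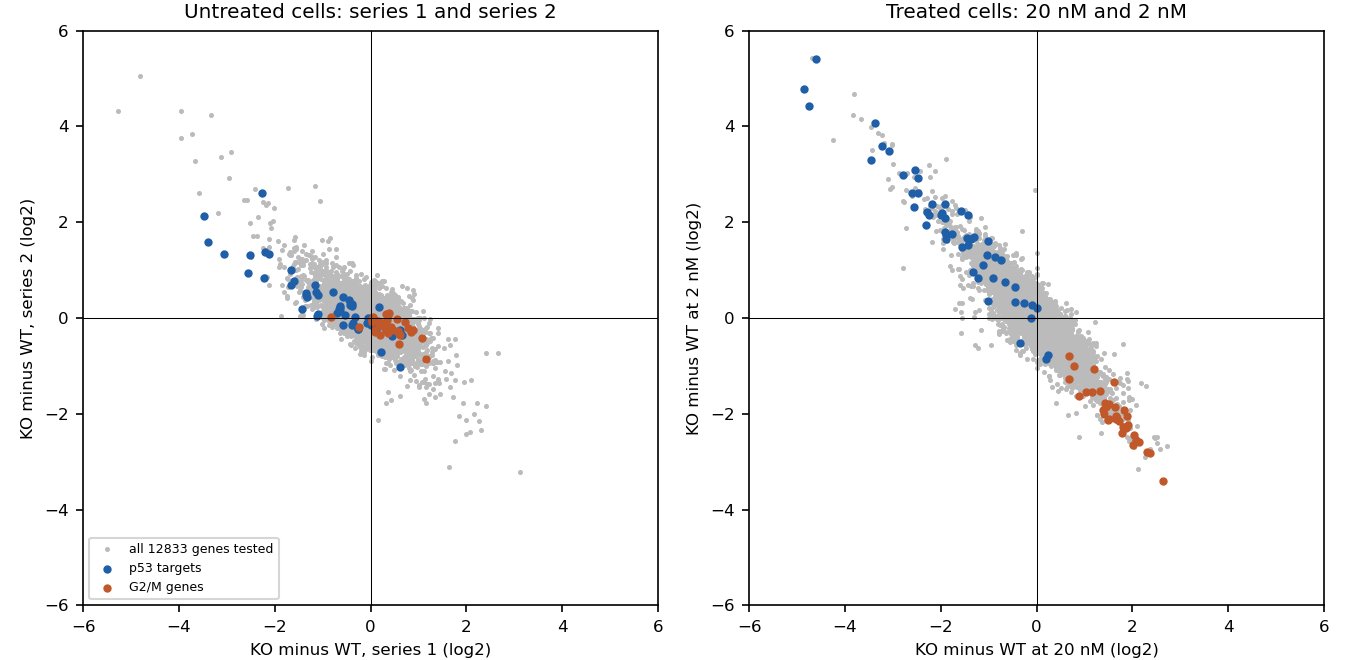
Each point is 1 of 12833 genes, placed by its KO minus WT log2 difference by label in the first and in the second slide series, for untreated arrays on the left panel and for treated arrays on the right panel. The p53 targets lie mostly in the upper left quadrant and the G2/M genes mostly in the lower right, and r across genes is -0.72 and -0.90.

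At 20 nM, WT-labelled cells had 2737 genes higher and 2875 lower than untreated WT-labelled arrays of the same series (n = 3 and 3), of which 1899 changed more than 2-fold. H4C14, a histone H4 gene, rose by 4.21 ± 0.08, from a mean intensity of 35.0 to 648.6 (adjusted p = 1.2e-17). GPR3, a receptor that raises cyclic AMP, rose by 3.99 ± 0.25, and SIK1, a kinase induced by cyclic AMP, by 3.94 ± 0.30. The histone H2A gene H2AC18 rose by 3.58 ± 0.34, SLC30A1, a zinc exporter, by 3.48 ± 0.31, ATP5MK, a small subunit of mitochondrial ATP synthase, by 3.50 ± 0.14, and RPL32, a ribosomal protein gene, by 3.41 ± 0.25. The RPL32 probe was dim, rising from a mean intensity of 23.9 to 254.1, while cytosolic ribosomal protein genes had a median intensity of 16951.6 over all arrays. It may therefore not read the main RPL32 transcript, which was not tested. The ATP5MK probe had an untreated mean of 71.3, while oxidative phosphorylation genes had a median intensity of 4227.5 over all arrays. The same limit applies to ATP5MK in every response. C9orf152 was at least 11.8-fold higher. RHBDL3, a rhomboid protease gene, was at least 11.2-fold lower. CCNF, which encodes cyclin F, fell by 3.43 ± 0.13. CYP24A1, the vitamin D 24-hydroxylase, was at -3.19 ± 0.18, the transcription factor gene MYB at -3.06 ± 0.33, EVI5L, a Rab GTPase-activating protein, at -3.02 ± 0.25, and SLC7A1, a cationic amino acid transporter, at -3.02 ± 0.24. REEP1, an endoplasmic reticulum-shaping protein, fell by 3.01 ± 0.28. SH3PXD2A, a podosome scaffold, was at -3.00 ± 0.28.

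Of 51 p53 targets, 28 rose and 3 fell (30 and 4 adjusted over the list alone; median 0.89, camera adjusted p = 2.3e-05, adjusted p = 0.732 with an estimated correlation). Without untreated replicate 4, where these targets were at -1.13 against arrays 5 and 6, the median was 0.44 (adjusted p = 0.0062). SESN1, a sestrin that restrains mTORC1, rose by 2.99 ± 0.29, PLK2, a polo-like kinase, by 2.47 ± 0.22 and PRKAB1, an AMPK subunit, by 2.04 ± 0.27. SUSD6 rose by 1.84 ± 0.31 and MDM2, which was dim, by 1.63 ± 0.31, from a mean intensity of 23.2 to 64.5. CDKN1A was at 0.59 ± 0.37 (adjusted p = 0.229), from a mean intensity of 13615.6 in untreated arrays, and at -0.005 without untreated replicate 4, whose intensity was 5212. Untreated replicates 5 and 6, at 17672 and 17963, already lay within the range of the treated arrays (16770 to 18949). GDF15 was at 8043 and 8320 on them against 1144 on replicate 4. Which of these controls is unusual was not tested, so a missing CDKN1A response cannot be read from them. Of 36 G2/M genes, 31 fell and 2 rose (31 and 2 adjusted over the list alone; median -1.29, adjusted p = 5.6e-14, adjusted p = 0.0269 with an estimated correlation). BUB1B, a spindle checkpoint kinase, fell by 2.87 ± 0.14. The mitotic kinesin KIF11 was at -2.54 ± 0.14, the phosphatase CDC25B at -2.30 ± 0.36 and topoisomerase TOP2A at -1.99 ± 0.10. Of 41 G1/S and DNA replication genes, 31 fell and 2 rose (33 and 4 adjusted over the list alone; median -1.004, adjusted p = 1.8e-11, adjusted p = 0.0177 with an estimated correlation). Among them CDT1, a replication licensing factor, fell by 2.92 ± 0.26. The chromatin assembly subunit CHAF1A was at -2.58 ± 0.15, the DNA polymerase alpha subunit POLA2 at -2.54 ± 0.19 and E2F2 at -2.38 ± 0.15.

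Histone genes rose in 15 and fell in 2 of 17 members (also 15 and 2 adjusted over the list alone; median 1.79, adjusted p = 1.9e-11, adjusted p = 3.3e-04 with an estimated correlation). Besides H4C14 and H2AC18, the H2B genes H2BC11 and H2BC12 rose by 2.99 ± 0.16 and 2.64 ± 0.14. All 4 genes listed beforehand as markers of XPO1 inhibition rose, also over the list alone (median 1.58, adjusted p = 0.00446, adjusted p = 0.0251 with an estimated correlation): NGFR, a neurotrophin receptor, by 2.53 ± 0.07, ARRDC3, an arrestin-domain protein, by 2.20 ± 0.36, the amino acid transporter SLC43A2 by 0.96 ± 0.21 and XPO1 itself by 0.48 ± 0.15. The XPO1 call was lost without untreated replicate 6 or treated replicate 3 (adjusted p = 0.0751 and 0.0842), and with slide as a random block (0.121). Of 26 DNA repair genes, 12 fell and 1 rose (12 and 1 adjusted over the list alone; median -0.35, adjusted p = 0.00995, adjusted p = 0.0251 with an estimated correlation). BRCA1 was at -2.45 ± 0.16, the helicase BLM at -2.25 ± 0.18, the mismatch repair gene MSH6 at -1.82 ± 0.08 and XRCC3 at -1.54 ± 0.31. Without untreated arrays 4 and 10 the DNA repair list had an adjusted p of 0.053.

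ATF4 and unfolded protein response genes fell in 18 and rose in 2 of 31 members (18 and 2 adjusted over the list alone; median -0.80, adjusted p = 7.9e-04, adjusted p = 0.796 with an estimated correlation). HERPUD1, an endoplasmic reticulum degradation factor, fell by 2.50 ± 0.36. Asparagine synthetase ASNS was at -2.38 ± 0.38, STC2 at -2.05 ± 0.62 and the transcription factor gene XBP1 at -1.93 ± 0.22. On untreated WT-labelled array 4 this list was at -1.27 against arrays 5 and 6. With array 4 alone as the control the median was -0.02, and without array 6 it was -0.50. Ribosome biogenesis genes rose in 21 and fell in 6 of 42 members (21 and 6 adjusted over the list alone; median 0.48, adjusted p = 0.0454, adjusted p = 0.867 with an estimated correlation). The kinase RIOK2 was at 2.88 ± 0.36, WDR74 at 1.65 ± 0.21, LYAR at 1.42 ± 0.25 and WDR75 at 1.39 ± 0.34. This call was lost without WT-labelled untreated replicate 4 or 6 or treated replicate 3 (adjusted p = 0.0649, 0.0545 and 0.0757). The nuclear export and import machinery had 7 members higher and 14 lower of 38 (8 and 15 adjusted over the list alone; median -0.19, adjusted p = 0.141). The importin KPNA4 fell by 1.35 ± 0.30. The pre-microRNA exporter XPO5 was at -1.06 ± 0.22, the importin-alpha exporter CSE1L at -0.99 ± 0.11 and the importin KPNB1 at -0.98 ± 0.09.

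No fibroblast marker changed (4 tested, largest COL5A1 at 0.19 ± 0.19), and of 7 blood and endothelial markers 2 rose, CD14 by 1.06 ± 0.12 and the globin gene HBA1 by 0.64 ± 0.23. Treated and untreated arrays of series 1 shared no slide, so slide could enter only as a random block, which gave 4087 genes. With slide as the block the medians were 0.80 for p53 targets, -1.34 for G2/M genes and 1.77 for histone genes.

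**Figure D2:**
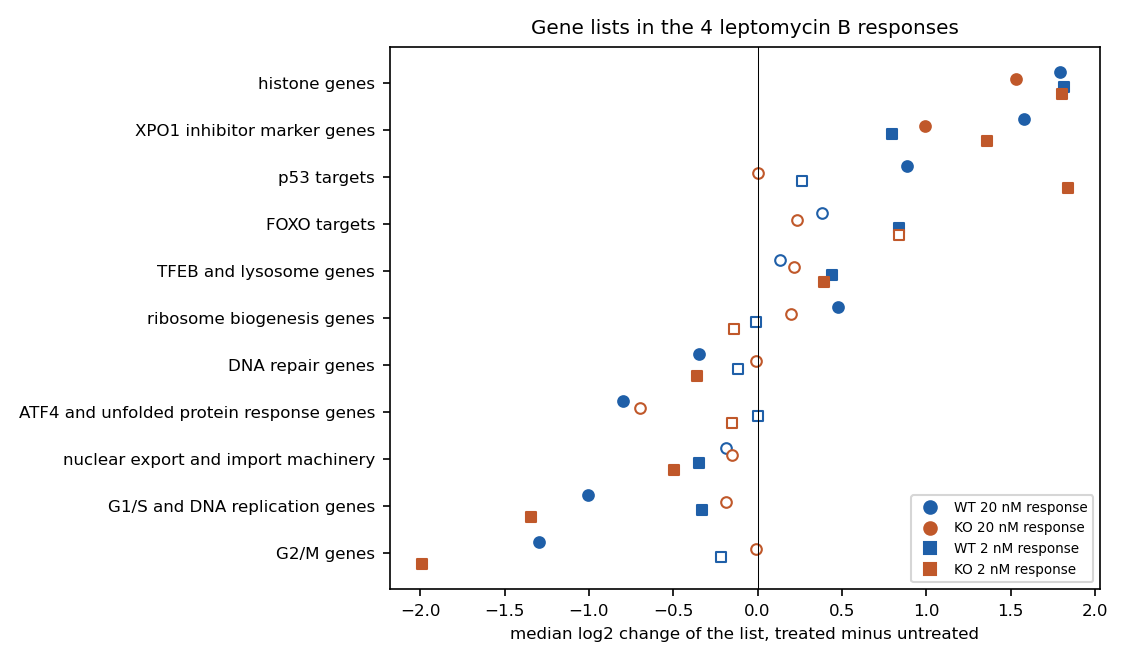
Median log2 change (horizontal axis) of 11 gene lists in the 4 leptomycin B responses, treated minus untreated, with blue for WT-labelled and orange for KO-labelled arrays, circles for 20 nM and squares for 2 nM. Filled symbols passed camera at an adjusted p under 0.05 with the preset correlation. Histone genes lie between 1.54 and 1.82 in all 4 responses, and G2/M genes between -1.99 and -0.01.

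At 20 nM in KO-labelled cells, 2386 genes were higher and 2445 lower (n = 3 and 3), 1253 of them by more than 2-fold. C9orf152 rose by 3.31 ± 0.09 (adjusted p = 2.6e-15), the metallothionein MT1X, a zinc-binding protein, by 3.17 ± 0.48, HCST, a signalling adaptor, by 2.99 ± 0.15 and ATP5MK by 2.94 ± 0.14. The untreated mean of C9orf152 was 8.5, under the floor of 10, so its SE and p may be too small. H4C14 rose by 2.91 ± 0.08, GPR3 by 2.91 ± 0.25, SLC30A1 by 2.86 ± 0.31 and the metallothionein pseudogene MT1P3 by 2.75 ± 0.42. NEK6, a mitotic kinase, fell by 3.31 ± 0.36. CLEC16A, a regulator of mitophagy, was at -2.75 ± 0.10, GTF2IRD1 at -2.69 ± 0.13, EVI5L at -2.69 ± 0.25 and SLC17A5, the lysosomal sialic acid exporter, at -2.59 ± 0.09. RHBDF2 fell by 2.51 ± 0.08. CELSR3 was at -2.46 ± 0.29 and the retinoid X receptor gene RXRA at -2.43 ± 0.11. MT1X and MT1P3 share near-identical sequence with other metallothionein genes, so their probes may not be specific.

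Histone genes rose in 12 and fell in 1 of 17 members (12 and 1 adjusted over the list alone; median 1.54, adjusted p = 6.2e-08, adjusted p = 0.00215 with an estimated correlation). H2BC12 was at 2.37 ± 0.14, H2AC18 at 2.29 ± 0.34 and H2BC21 at 2.13 ± 0.22. Of the 4 XPO1 inhibition markers 3 rose, and 4 adjusted over the list alone (median 0.99, adjusted p = 0.0493, adjusted p = 0.118 with an estimated correlation). ARRDC3 rose by 1.65 ± 0.36, NGFR by 1.44 ± 0.07 and SLC43A2 by 0.54 ± 0.21, and XPO1 was at 0.32 ± 0.15 (adjusted p = 0.111). Of 51 p53 targets 7 rose and 4 fell (6 and 2 adjusted over the list alone; median 0, adjusted p = 0.875). PLK2 was at 1.52 ± 0.22, FBXO22 at 1.01 ± 0.20, IER5 at 1.00 ± 0.19 and RPS27L at 0.93 ± 0.13. CDKN1A was at -0.51 ± 0.37 (adjusted p = 0.322) and MDM2 at -0.51 ± 0.31 (adjusted p = 0.215). Both depended on untreated replicate 4: without it CDKN1A was at -0.978 (adjusted p = 0.0283) and MDM2 at -0.811 (0.0446). MDM2 lay near the floor of 10, with mean intensities of 14.9 untreated and 9.8 treated, so its change rests on dim values. With replicate 4 as the only control, a single array, CDKN1A was at 0.417. Without untreated replicate 5 or 6 CDKN1A was at -0.266 and -0.295, and without 6 MDM2 was at -0.301. G2/M genes had a median of -0.01, with 7 of 36 higher and 8 lower, also over the list alone (adjusted p = 0.931). The median of the p53 targets was 0 and their mean -0.004, while camera's direction was up; the mean of the G2/M genes was 0.03, while median and camera pointed down. The nuclear export and import machinery had 3 members higher and 9 lower, also over the list alone (median -0.15, adjusted p = 0.512). KPNA4 was at -1.24 ± 0.30, XPO5 at -1.18 ± 0.22, the nucleoporin NUP214 at -0.96 ± 0.15 and the importin KPNA2 at -0.95 ± 0.22. No fibroblast marker was called (largest COL5A1 at 0.21 ± 0.19), while HBA1 rose by 2.04 ± 0.23 and CD14 by 1.20 ± 0.12. The call of the XPO1 marker list was lost without untreated arrays 4 and 10 (adjusted p = 0.0624) or treated replicate 2 (0.0527). With only the compared arrays in the fit 3164 genes were called, and with array weights 7614.

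The direct test of the genotype label at 20 nM, the WT response minus the KO response, gave 512 genes higher and 643 lower. MDM2 responded more strongly under the WT label by 2.14 ± 0.43 (adjusted p = 0.00316), SESN1 by 2.24 ± 0.41, ANKRD30BL by 2.37 ± 0.28, AKAP19 by 2.34 ± 0.20, H3C13, a histone H3 gene, by 2.14 ± 0.22 and ABCA1, a cholesterol exporter, by 2.13 ± 0.41. Under the KO label MDM2 lay near the floor of 10, as given above. The difference was -2.62 ± 0.26 for the adhesion receptor ADGRF1, -2.37 ± 0.35 for the homeobox gene IRX3, -2.26 ± 0.54 for cyclin E2 (CCNE2), -2.24 ± 0.19 for the kinetochore gene SPC25, -2.23 ± 0.45 for FRAT2 and -2.16 ± 0.26 for the DNA glycosylase NEIL3. CDKN1A differed by 1.10 ± 0.52 (adjusted p = 0.238, and by 0.508 without WT-labelled untreated replicate 4) and XPO1 by 0.15 ± 0.22 (adjusted p = 0.84).

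The p53 targets differed by a median of 0.87, with 13 of 51 higher (21 adjusted over the list alone; adjusted p = 1.6e-09, adjusted p = 0.376 with an estimated correlation). Without WT-labelled untreated replicate 4 their median was 0.508 (adjusted p = 3.5e-04). SUSD6 was at 1.97 ± 0.44 and TIGAR at 1.72 ± 0.33. G2/M genes differed by -1.38, with 30 of 36 lower (32 over the list alone; adjusted p = 7.3e-38, adjusted p = 6.4e-04 with an estimated correlation). BUB1B was at -2.03 ± 0.20 and CENPA, the centromeric histone H3 variant, at -1.93 ± 0.24. G1/S genes differed by -0.83 with 27 of 41 lower (34 over the list alone; adjusted p = 2.5e-24, adjusted p = 6.4e-04 with an estimated correlation). DNA repair genes differed by -0.45 with 9 of 26 lower (11 lower and 1 higher over the list alone; adjusted p = 6.6e-05, adjusted p = 8.2e-04 with an estimated correlation). Histone genes differed by 0.64 with 9 of 17 higher and 2 lower (12 and 2 over the list alone; adjusted p = 1.4e-08, adjusted p = 7.0e-04 with an estimated correlation). The XPO1 markers differed by 0.48 (NGFR called at 1.09 ± 0.10; adjusted p = 0.0261, adjusted p = 0.0652 with an estimated correlation). ATF4 genes differed by -0.39 with 2 of 31 lower, PHGDH at -1.51 ± 0.38 and CEBPG at -1.16 ± 0.27 (also 2 over the list alone; adjusted p = 0.0321, adjusted p = 0.869 with an estimated correlation). BCL2 family and caspase genes differed by 0.15 with 6 higher and 1 lower of 31 (7 and 2 over the list alone; adjusted p = 0.0321, adjusted p = 0.712 with an estimated correlation). APAF1 was at 1.68 ± 0.24 and the death receptor FAS at 1.67 ± 0.16. The export and import machinery (median -0.07, NUP107 at -0.45 ± 0.10) and both sets of other cell type markers did not pass. Without untreated arrays 4 and 10 the difference held 4366 genes, and without KO-labelled array 4 alone 2602, while slide as a random block gave 612. With that block the median was -0.276 for DNA repair genes, 0.09 for BCL2 family and caspases and 0.654 for p53 targets. With only untreated arrays 4 and 10 as controls, which leaves 1 control array per label here, ATF4 genes turned to 0.134. Without WT-labelled array 4 they were at -0.841, without 5 at -0.166 and without 6 at -0.188. BCL2 family and caspases were at 0, 0.254 and 0.277 without WT-labelled array 4, 5 or 6, and at 0.303 and 0.102 without KO-labelled array 4 or 6. Single arrays ended the calls of 3 lists, with adjusted p = 0.0679 for the XPO1 markers without KO-labelled untreated replicate 4. It was 0.0519 to 0.417 for ATF4 genes without WT-labelled untreated replicate 5 or 6, WT-labelled treated replicate 1, KO-labelled untreated replicate 4 or KO-labelled treated replicate 3. It was 0.0515 to 0.313 for BCL2 family and caspases without WT-labelled untreated replicate 4, WT-labelled treated replicate 1 or KO-labelled untreated replicate 5 or 6.

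At 2 nM, WT-labelled cells had 2259 genes higher and 2483 lower (n = 3 and 4), 1183 of them by more than 2-fold. H2AC18 rose by 3.91 ± 0.32 (adjusted p = 1.7e-08), FOSB, an AP-1 subunit of the immediate early class, by 3.22 ± 0.70, SIK1 by 3.17 ± 0.28 and HCST by 3.16 ± 0.14. TENT5C, a poly(A) polymerase, rose by 3.13 ± 0.22, H2BC21 by 3.11 ± 0.20 and ARRDC3 by 3.10 ± 0.34. C9orf152 was at least 12.9-fold higher. FAAP100, a Fanconi anaemia core complex subunit, fell by 2.85 ± 0.39. The ubiquitin ligase gene SH3RF2 was at -2.46 ± 0.21, CTC1, a telomere maintenance factor, at -2.46 ± 0.27, POLA2 at -2.40 ± 0.18 and IGF2BP3, an RNA-binding protein, at -2.32 ± 0.28. LETM2 fell by 2.31 ± 0.44. THEM6 was at -2.28 ± 0.25 and EMG1, a ribosomal RNA methyltransferase, at -2.26 ± 0.20.

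Histone genes rose in 12 and fell in 1 of 17 members (12 and 1 adjusted over the list alone; median 1.82, adjusted p = 6.4e-10, adjusted p = 6.0e-04 with an estimated correlation). FOXO targets rose in 9 of 19 members (12 over the list alone; median 0.84, adjusted p = 1.3e-04, adjusted p = 0.0891 with an estimated correlation). The insulin receptor substrate gene IRS2 was at 3.01 ± 0.49, CITED2 at 2.50 ± 0.26, BCL6 at 2.27 ± 0.52 and the ubiquitin ligase gene FBXO32 at 2.07 ± 0.28. TFEB and lysosome genes rose in 15 and fell in 2 of 25 members (15 and 3 over the list alone; median 0.44, adjusted p = 0.00372, adjusted p = 0.231 with an estimated correlation). The autophagosome gene MAP1LC3B was at 1.77 ± 0.36, cathepsin CTSL at 1.65 ± 0.11, RRAGD at 0.87 ± 0.13 and FLCN at 0.81 ± 0.20. TGF-beta targets rose in 6 and fell in 1 of 12 members (6 and 1 over the list alone; median 0.24, adjusted p = 0.0449, adjusted p = 0.19 with an estimated correlation). The pseudoreceptor BAMBI rose by 2.59 ± 0.11, BHLHE40 by 1.69 ± 0.50, TGIF1 by 0.88 ± 0.18 and SMAD7 by 0.70 ± 0.16. BAMBI, SMAD7 and TGIF1 are known as inhibitors of the pathway. The call was lost without untreated replicate 8 or 9 or treated replicate 3 (adjusted p = 0.053, 0.0556 and 0.0684).

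Of 41 G1/S genes, 19 fell and 7 rose (22 and 8 over the list alone; median -0.33, adjusted p = 0.0136, adjusted p = 0.489 with an estimated correlation). The replication factor CDC45 was at -1.70 ± 0.18 and CHAF1A at -1.62 ± 0.14 against cyclin E1 (CCNE1) at 1.62 ± 0.26. The export and import machinery fell in 18 and rose in 3 of 38 members (also over the list alone; median -0.35, adjusted p = 0.0107, adjusted p = 0.65 with an estimated correlation). XPO5 was at -1.20 ± 0.21, RANGAP1, the GTPase activator of Ran, at -1.14 ± 0.22, CSE1L at -0.95 ± 0.10 and the importin IPO8 at -0.88 ± 0.15. XPO1 rose by 0.59 ± 0.14 (adjusted p = 0.00287) and NGFR by 1.00 ± 0.06, and the 4 XPO1 markers had a median of 0.80 with 3 higher (3 over the list alone; adjusted p = 0.0197, adjusted p = 0.0891 with an estimated correlation). The p53 targets had 12 members higher and 3 lower of 51 (11 and 3 over the list alone; median 0.27, adjusted p = 0.146). TP53INP1 was at 1.89 ± 0.40, PLK2 at 1.61 ± 0.21, PMAIP1, a BH3-only protein, at 1.61 ± 0.50 and PPM1D at 1.53 ± 0.48. CDKN1A was at 0.80 ± 0.35 (adjusted p = 0.0789) and MDM2 at 0.43 ± 0.29 (adjusted p = 0.287). G2/M genes had a median of -0.22 with 12 lower and 6 higher of 36 (12 and 6 over the list alone; adjusted p = 0.189). HBA1 rose by 2.03 ± 0.22 and CD14 by 1.24 ± 0.11, the macrophage gene CD68 fell by 0.79 ± 0.12, and COL5A1, the largest fibroblast value, was at 0.07 ± 0.17. Slide 6 held all WT-labelled arrays of series 2, so treatment was compared within a slide. The call of the XPO1 marker list was lost without untreated arrays 4 and 10 (adjusted p = 0.0732).

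At 2 nM in KO-labelled cells, 2816 genes were higher and 2830 lower (n = 3 and 4), 1811 of them by more than 2-fold. SESN1 rose by 4.32 ± 0.27, from 55.6 to 1088.6 (adjusted p = 2.1e-10), SERPINB5, the p53-induced serpin maspin, by 4.18 ± 0.24 and the galanin receptor gene GALR2 by 4.11 ± 0.91. TP53I3, a p53-induced quinone oxidoreductase, rose by 3.81 ± 0.39, H2AC18 by 3.65 ± 0.32, ACTA2, smooth muscle actin and a p53 target, by 3.65 ± 0.26 and TP53INP1 by 3.60 ± 0.40. C9orf152 was at least 15.0-fold higher. BUB1B fell by 3.85 ± 0.13. CENPA was at -3.74 ± 0.16, ADGRF1 at -3.47 ± 0.17, the mitotic spindle gene CKAP2L at -3.37 ± 0.12, KIF11 at -3.24 ± 0.13, the kinesin KIF15 at -3.18 ± 0.13 and BRCA1 at -3.15 ± 0.15. CCNF was at least 9.44-fold lower. CDKN1A rose by 2.26 ± 0.35 (adjusted p = 2.2e-05), MDM2 by 2.66 ± 0.29, from 14.4 to 90.7, and XPO1 by 0.54 ± 0.14.

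Of 51 p53 targets, 46 rose and 1 fell (47 and 1 adjusted over the list alone; median 1.84, adjusted p = 4.6e-16, adjusted p = 0.114 with an estimated correlation), GADD45A, a DNA damage response gene, by 2.97 ± 0.50. Of 36 G2/M genes, 34 fell and none rose (35 over the list alone; median -1.99, adjusted p = 1.6e-26, adjusted p = 0.00362 with an estimated correlation). The centromere gene CENPF was at -2.93 ± 0.38. Of 41 G1/S genes, 31 fell and 2 rose (31 and 2 over the list alone; median -1.34, adjusted p = 6.2e-15, adjusted p = 0.00362 with an estimated correlation). The polymerase subunit POLE2 was at -3.02 ± 0.16, CDC45 at -3.01 ± 0.18, POLA2 at -2.99 ± 0.18 and MCM10 at -2.77 ± 0.16. Of 26 DNA repair genes, 12 fell and 1 rose (12 and 1 over the list alone; median -0.36, adjusted p = 2.0e-04, adjusted p = 0.00362 with an estimated correlation). BLM was at -2.15 ± 0.17 and MSH6 at -2.02 ± 0.08. Histone genes rose in 10 and fell in 2 of 17 members (10 and 2 over the list alone; median 1.81, adjusted p = 2.5e-05, adjusted p = 0.00669 with an estimated correlation). H2BC5 was at 3.44 ± 0.16, H4C14 at 2.89 ± 0.08 and H2BC12 at 2.84 ± 0.14. The 4 XPO1 markers all rose, also over the list alone (median 1.36, adjusted p = 0.00336, adjusted p = 0.0185 with an estimated correlation). ARRDC3 was at 3.27 ± 0.34 and NGFR at 2.06 ± 0.06.

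The export and import machinery fell in 24 and rose in 3 of 38 members (24 and 3 over the list alone; median -0.50, adjusted p = 5.7e-05, adjusted p = 0.394 with an estimated correlation). KPNA2 was at -1.86 ± 0.21, KPNA4 at -1.22 ± 0.28 and the nucleoporins NUP88 and NUP107 at -1.20 ± 0.08 and -1.20 ± 0.06. BCL2 family and caspase genes rose in 13 and fell in 5 of 31 members (13 and 6 over the list alone; median 0.41, adjusted p = 0.0421, adjusted p = 0.46 with an estimated correlation); APAF1, the apoptosome scaffold, rose by 2.88 ± 0.16, the death receptor TNFRSF10B by 2.27 ± 0.31, PMAIP1 by 2.21 ± 0.50 and BAK1 by 1.87 ± 0.24. TFEB and lysosome genes rose in 13 and fell in 2 of 25 members (13 and 3 over the list alone; median 0.40, adjusted p = 0.0421, adjusted p = 0.394 with an estimated correlation). CTSL was at 1.64 ± 0.11, MAP1LC3B at 1.29 ± 0.36, ATP6V1H at 1.25 ± 0.19 and TPP1 at 1.13 ± 0.18. Cytosolic ribosomal protein genes rose in 13 of 36 members (12 over the list alone; median 0.07, adjusted p = 0.00947, adjusted p = 0.289 with an estimated correlation). RPL32, read by the dim probe described above, was at 2.71 ± 0.24, RPL14 at 0.89 ± 0.19, RPL37 at 0.86 ± 0.10 and RPS23 at 0.74 ± 0.15. COL5A1, a collagen gene among the fibroblast markers, rose by 0.49 ± 0.17, HBA1 by 0.91 ± 0.22 and CD14 by 0.89 ± 0.11, and CD68 fell by 0.95 ± 0.12. Without KO-labelled untreated replicate 7 or 8 the calls of the BCL2 and caspase list (adjusted p = 0.0619 and 0.0507) and of the TFEB list (0.0619 and 0.0593) were lost.

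**Figure D3:**
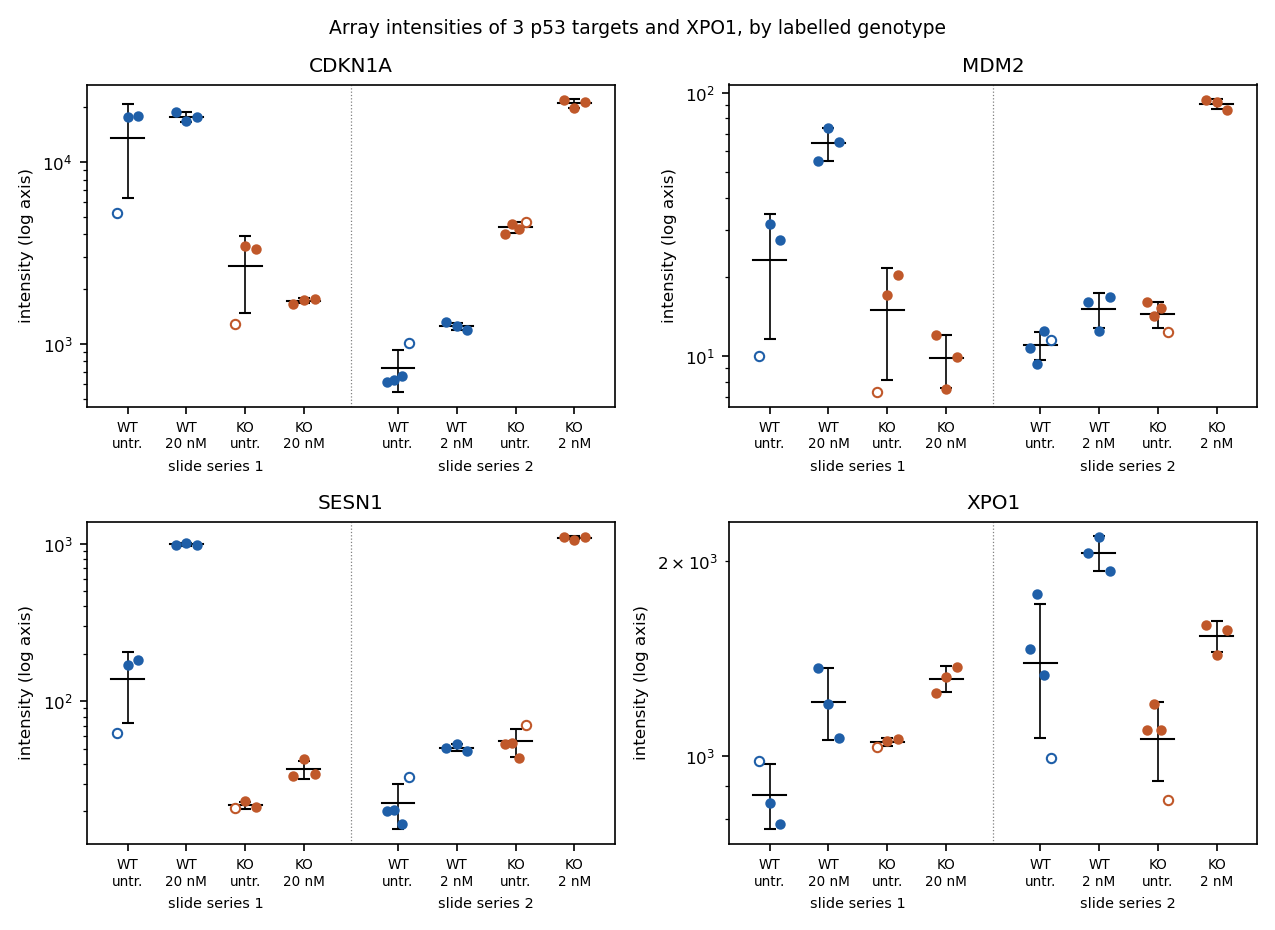
Intensity on a log axis of CDKN1A, MDM2, SESN1 and XPO1 on each of the 26 arrays, by labelled genotype (blue WT, orange KO), treatment and slide series; horizontal bars are means and error bars SD (n = 3 or 4), and open points are untreated arrays 4 and 10. SESN1 has a mean of 990.6 in WT-labelled cells at 20 nM and 1088.6 in KO-labelled cells at 2 nM, and 37.0 and 50.9 in the other treated groups.

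The same direct test at 2 nM gave 785 genes with a higher and 778 with a lower response under the WT label, the reverse of 20 nM for the p53 targets and cell cycle genes. CENPA differed by 3.31 ± 0.22 (adjusted p = 4.2e-09), ADGRF1 by 3.09 ± 0.24, RGS2, a regulator of G protein signalling, by 2.82 ± 0.48, the CENPA chaperone HJURP by 2.75 ± 0.19, BUB1B by 2.70 ± 0.19 and the kinetochore gene NDC80 by 2.60 ± 0.21. TP53I3 differed by -4.07 ± 0.56, SERPINB5 by -3.85 ± 0.33, ABCA1 by -3.46 ± 0.38, the adhesion molecule CEACAM1 by -3.40 ± 0.29, ACTA2 by -3.24 ± 0.36, the cytochrome P450 gene CYP4F3 by -3.19 ± 0.29 and MDM2 by -2.23 ± 0.41. CDKN1A differed by -1.46 ± 0.49 (adjusted p = 0.0597) and XPO1 by 0.06 ± 0.20.

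The p53 targets differed by a median of -1.58, with 32 of 51 lower and 1 higher (38 and 1 adjusted over the list alone; adjusted p = 1.0e-23, adjusted p = 0.0547 with an estimated correlation), SESN1 by -3.10 ± 0.39. G2/M genes differed by 1.85 with 35 of 36 higher (36 over the list alone; adjusted p = 1.1e-55, adjusted p = 1.2e-04 with an estimated correlation). G1/S genes differed by 0.94 with 30 of 41 higher (34 over the list alone; adjusted p = 6.8e-25, adjusted p = 3.0e-04 with an estimated correlation). DNA repair genes differed by 0.37 with 9 of 26 higher (10 over the list alone; adjusted p = 2.8e-05, adjusted p = 6.2e-04 with an estimated correlation). MCM10 differed by 2.03 ± 0.22 and EXO1, an exonuclease of mismatch repair, by 1.85 ± 0.26. The export and import machinery differed by 0.23 with 6 of 38 higher, KPNA2 by 1.13 ± 0.29 (8 higher and 2 lower over the list alone; adjusted p = 0.00857, adjusted p = 0.54 with an estimated correlation). BCL2 family and caspase genes differed by -0.19, with 8 lower and 3 higher of 31 (9 and 4 over the list alone; adjusted p = 0.0392, adjusted p = 0.54 with an estimated correlation), FAS by -1.73 ± 0.15. Splicing and mRNA export genes differed by 0.11 with 2 of 29 higher, DDX39A at 0.62 ± 0.15 and SRSF10 at 0.55 ± 0.15 (7 over the list alone; adjusted p = 0.0392, adjusted p = 0.321 with an estimated correlation). Fibroblast and blood markers did not pass, although HBA1 differed by 1.12 ± 0.31. Each of the 2 responses was taken within 1 slide, and slide as a random block gave 1847 genes. Without untreated arrays 4 and 10 the difference held 3965 genes. The call of the export and import machinery was lost without WT-labelled untreated replicate 10 (median 0.151, adjusted p = 0.103). BCL2 family and caspases were at -0.296 without untreated replicate 10 of either label. Those of the BCL2 and caspase list and of the splicing list were lost without any of several single arrays of both labels, among them WT-labelled treated replicate 2 (0.0588 and 0.0562), WT-labelled treated replicate 3 (0.0586 and 0.0568), KO-labelled treated replicate 2 (0.0506 and 0.0608) and KO-labelled untreated replicates 7 (0.0548 for both) and 9 (0.0543 and 0.0575). The splicing call was also lost without WT-labelled untreated replicate 10 (0.0889) or KO-labelled untreated replicate 8 (0.0685).

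The KO minus WT differences of treated arrays likewise opposed each other. At 20 nM CDKN1A was at -3.37 ± 0.37 in KO-labelled arrays and at 2 nM at 4.07 ± 0.37, GDF15 at -4.85 ± 0.51 and 4.79 ± 0.51, and CENPA at 2.65 ± 0.17 and -3.40 ± 0.17. In all, 2332 of the 2347 genes called at both doses had opposite signs, where independent lists would give 429, and r across genes was -0.90 (rho -0.79).

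**Figure D4:**
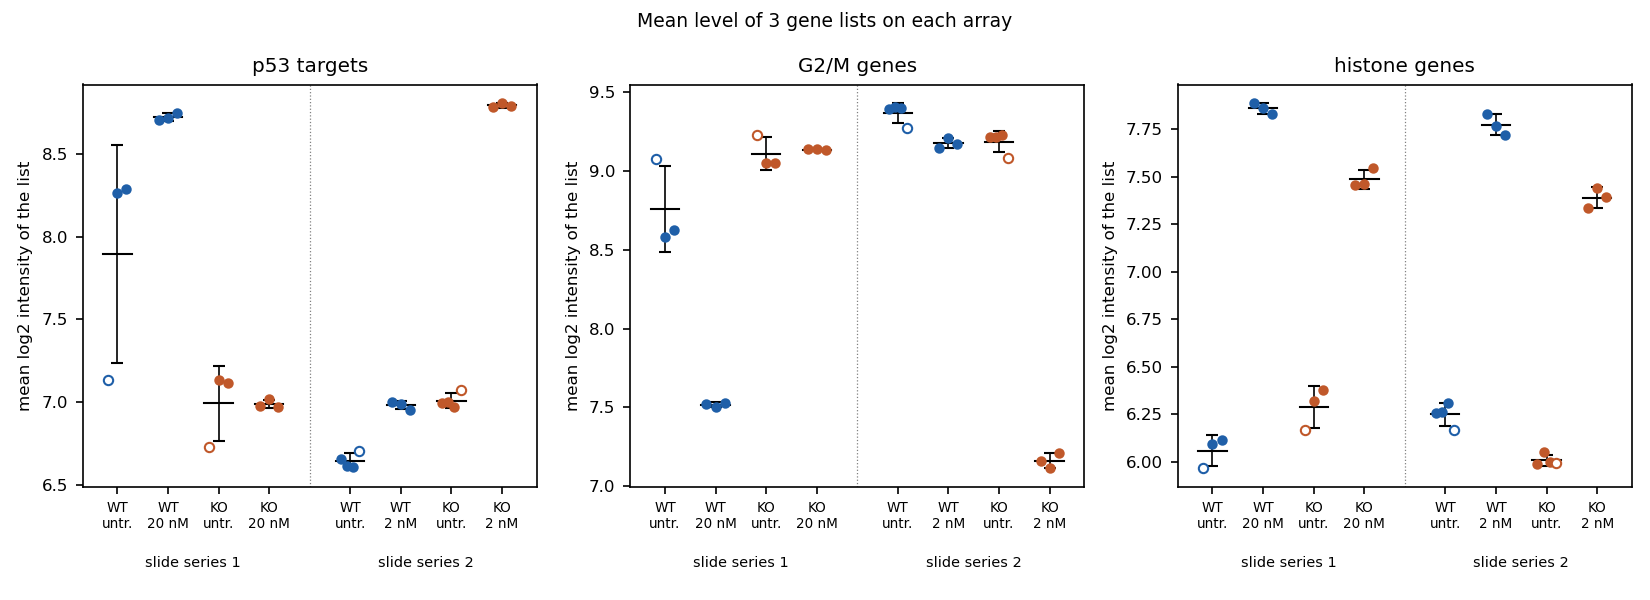
Mean log2 intensity of the p53 targets, G2/M genes and histone genes on each of the 26 arrays, by labelled genotype, treatment and slide series, with bars for means and SD (n = 3 or 4) and open points for untreated arrays 4 and 10. G2/M genes are lowest and p53 targets highest in WT-labelled cells at 20 nM and KO-labelled cells at 2 nM, and histone genes are higher in all 4 treated groups.

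Dose was compared as the 20 nM minus the 2 nM response within each label, across slide series. Dose and series coincide, and responses were taken across slides at 20 nM and within a slide at 2 nM. A difference of responses can therefore come from dose, series or slide. Genotype differences also opposed each other between the series, so 1 label may not stand for the same genotype at both doses. Under the WT label 1248 genes responded more positively and 1290 more negatively at 20 nM. SERPINB5 differed by 2.72 ± 0.35, AKAP19 by 2.70 ± 0.20, ANKRD30BL by 2.68 ± 0.27, INKA1 by 2.53 ± 0.37, MT1P3 by 2.53 ± 0.58 and H3C13 by 2.48 ± 0.21. FRAT2 differed by -3.32 ± 0.43, IRX3 by -3.19 ± 0.34, the hypoxia-induced genes BNIP3L and ANKRD37 by -3.19 ± 0.64 and -2.90 ± 0.72, the kinase inhibitor CDKN2D by -2.88 ± 0.92 and RHBDL3 by -2.86 ± 0.33. CDKN1A differed by -0.22 ± 0.51 (and by -0.807 without untreated replicate 4), MDM2 by 1.20 ± 0.42 (adjusted p = 0.0502, and by 0.682 without that array) and XPO1 by -0.12 ± 0.21. Without untreated arrays 4 and 10 of both labels CDKN1A was called at -0.975 (limma adjusted p = 1.2e-07) and MDM2 at 0.667 (0.011). With replicate 4 left out, the 20 nM controls are untreated replicates 5 and 6, whose CDKN1A already lay within the range of the treated arrays. The CDKN1A values without replicate 4 can therefore not be read as an effect of dose. The list medians were 0.39 for p53 targets (16 of 51 higher, 19 over the list alone), -1.18 for G2/M genes (28 of 36 lower, 32 over the list alone) and -0.63 for G1/S genes (24 of 41 lower, 25 lower and 1 higher over the list alone). They were 0.35 for histone genes, -0.29 for DNA repair genes, 0.55 for ribosome biogenesis genes and 0.24 for heat shock genes. Medians were -0.93 for ATF4 genes, -0.73 for immediate early genes, -0.69 for FOXO targets, -0.24 for TFEB genes and -0.87 for hypoxia genes. All 12 lists passed camera, and with an estimated correlation only G2/M and G1/S genes passed (adjusted p = 0.0115 for both). Adjusted p was 0.6 for p53 targets, 0.15 for histones, 0.0505 for DNA repair, 0.618 for ribosome biogenesis, 0.477 for heat shock, 0.6 for ATF4 and hypoxia, 0.371 for immediate early and TFEB and 0.231 for FOXO, with an estimated correlation. On untreated WT-labelled array 4 hypoxia genes were at -1.26, ATF4 genes at -1.27 and p53 targets at -1.13 against arrays 5 and 6. Without that array p53 targets had a median of 0.15 (adjusted p = 0.293), ATF4 genes one of -1.597 and histone genes an adjusted p of 0.0596. Without array 5 or 6 p53 targets were at 0.686 and 0.669. With slide as a random block DNA repair genes were at -0.172. Without untreated arrays 4 and 10 of both labels adjusted p was 0.526 for p53 targets, 0.315 for histone genes and 0.129 for DNA repair genes. In that setting the medians were -1.328 for hypoxia genes, -1.698 for ATF4 genes and -0.377 for TFEB genes. CDKN2D lost its call without any 1 of 10 arrays (adjusted p = 0.0524 to 0.104), namely the 3 at 20 nM, the 3 at 2 nM and untreated replicates 5, 6, 7 and 8.

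Under the KO label 1362 genes responded more positively and 1427 more negatively at 20 nM. CENPA differed by 3.76 ± 0.23, ADGRF1 by 3.29 ± 0.25, CENPF by 3.27 ± 0.55, ARHGEF39 by 3.16 ± 0.55, BUB1B by 3.02 ± 0.20 and HJURP by 3.01 ± 0.20. The mTORC1 inhibitor DDIT4 differed by -4.73 ± 0.90, GALR2 by -4.18 ± 1.34, TP53I3 by -3.96 ± 0.58, GDF15 by -3.87 ± 0.70, the melanocortin receptor gene MC1R by -3.78 ± 0.31, CSRNP1 by -3.56 ± 1.09, MDM2 by -3.17 ± 0.42 and CDKN1A by -2.78 ± 0.51. List medians were -2.02 for p53 targets (38 of 51 lower, 42 over the list alone), 2.08 for G2/M genes (36 of 36 higher, also over the list alone) and 0.98 for G1/S genes (31 of 41 higher, 37 higher and 1 lower over the list alone). They were 0.63 for DNA repair genes and 0.43 for the export and import machinery (14 of 38 higher, 15 over the list alone). Medians were -0.93 for NF-kB targets, 0.35 for ribosome biogenesis, -0.12 for cytosolic ribosomal proteins, -0.43 for BCL2 family and caspases and -0.79 for hypoxia genes. All 10 passed camera, and with an estimated correlation only G2/M, G1/S and DNA repair genes passed (adjusted p = 5.5e-04, 5.7e-04 and 5.5e-04). Adjusted p was 0.0776 for p53 targets, 0.391 for the export machinery, 0.47 for NF-kB, 0.788 for ribosome biogenesis, 0.0862 for ribosomal proteins, 0.387 for BCL2 and caspases and 0.767 for hypoxia, with an estimated correlation. On untreated KO-labelled array 4 the NF-kB and hypoxia lists were at -1.01 and -1.17 against arrays 5 and 6. Without that array ribosome biogenesis genes had an adjusted p of 0.195, without untreated replicate 7, 8 or 9 0.0831, 0.0978 and 0.0801, and hypoxia genes had 0.058 without untreated replicate 5 (median -0.523). The hypoxia median was -1.292 without untreated arrays 4 and 10 of both labels. CSRNP1 lost its call without untreated replicate 5 or 6 or 20 nM replicate 1 (0.0876, 0.0878 and 0.0507), and GALR2 without untreated replicate 5 or 6 or any treated array (0.0505 to 0.0965). Other cell type markers passed in neither dose comparison. Without untreated arrays 4 and 10 the counts of the WT and KO dose comparisons were 5755 and 6226. The KO count was 4423 without KO-labelled array 4 alone and 1713 with slide as a random block, and with the genotype names of series 2 exchanged, an alternative chosen after seeing the data, 1124 and 843.

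A set of 1067 genes rose and 1142 fell in all 4 responses, where independent calls would give 19.7 and 23.4. H2AC18 rose by 2.29 to 3.91, SIK1 by 2.62 to 3.94, SGK1, a glucocorticoid-induced kinase, by 1.73 to 3.09, and BAMBI by 2.18 to 2.59. EXOC6, an exocyst subunit, ranged from -2.81 to -2.19 over the 4 responses, IGF2BP3 from -2.95 to -2.03 and the alanyl-tRNA synthetase AARS1 from -2.66 to -1.61. SGK1, EXOC6 and AARS1 were picked from the largest common changes after their values were seen. Across genes, which are not independent replicates, the responses of WT-labelled cells at 20 nM and KO-labelled cells at 2 nM had r = 0.81, the 2 labels at 20 nM 0.79 and the 2 labels at 2 nM 0.76. It was 0.66 for the 2 doses under the WT label, 0.57 for the 2 doses under the KO label and 0.69 for KO-labelled cells at 20 nM with WT-labelled cells at 2 nM. None of these pairs of responses shares an array.

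Several lists passed camera in none of the comparisons of untreated genotype labels, of treated with untreated arrays, or of responses by genotype or dose. Among them, YAP targets, cholesterol synthesis genes and oxidative phosphorylation genes did pass with the preset correlation in comparisons among untreated arrays of the same label and series, taken up below. In WT-labelled cells at 20 nM the medians were -0.30 for 19 cholesterol synthesis genes (4 higher and 5 lower, 4 and 6 adjusted over the list alone; camera adjusted p = 0.555) and -0.36 for 21 NRF2 targets (4 and 7, 4 and 9 over the list alone; 0.449). They were 0 for 16 intestinal epithelial genes (6 and 1, also over the list alone; 0.449) and 0.39 for 14 YAP targets (none and 2, also over the list alone; 0.684). Medians were 0.15 for 35 oxidative phosphorylation genes (13 and 6, also over the list alone; 0.342), 0.01 for 11 housekeeping genes, with camera's direction down (2 and 2, also over the list alone; 0.793), and 0.01 for 14 Wnt targets, whose mean was -0.02 (3 and 2, also over the list alone; 0.747).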

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

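The tests on the opposite genotype differences and on arrays 4 and 10, and the splits that part both, were chosen only after the results were seen; the counts over other splits of the arrays were planned.

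The response to 20 nM differed between the labels in 1155 genes by the direct test, with median differences of 0.874 for p53 targets, 0.483 for XPO1 markers, -1.383 for G2/M genes, -0.827 for G1/S genes, 0.639 for histone genes, -0.393 for ATF4 genes, 0.154 for BCL2 family and caspases and -0.446 for DNA repair genes. With an estimated correlation between genes p53 targets (adjusted p = 0.376), XPO1 markers (0.0652), ATF4 genes (0.869) and BCL2 family and caspases (0.712) did not pass. The response to 2 nM differed in 1563 genes, with -1.576 for p53 targets, 0.227 for the export and import machinery, 1.849 for G2/M genes, 0.943 for G1/S genes, -0.187 for BCL2 family and caspases, 0.374 for DNA repair genes and 0.105 for splicing and mRNA export genes, of which p53 targets (0.0547), the export machinery (0.54), BCL2 family and caspases (0.54) and splicing genes (0.321) did not pass in this way.

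The genotype differences of the 2 slide series opposed each other in untreated and treated arrays. An additive difference between slide series would leave the within-series differences alike, and r across genes stayed at or below -0.565 with any 1 untreated array left out, which argues against it. The different leptomycin B dose is argued against as well, since the differences opposed each other in untreated arrays, which received none (r = -0.72). The KO minus WT difference of untreated arrays 4 against that of untreated arrays 10 had r = -0.83. This is part of the same pattern and no separate evidence. Genotype names exchanged on the slides of 1 series would turn every gene alike. Across 12679 genes outside the p53, cell cycle and DNA repair lists r was -0.712 in untreated and -0.886 in treated arrays, but this nearly restates r over all genes and tests nothing further. Labels that stood for the same genotypes in both series would give differences that run alike. Instead 667 of 668 genes called in both series had opposite signs in untreated arrays, and 2332 of 2347 in treated arrays, where dose differed too. These values argue against labels that hold in both series. How the labels came to differ is not shown, so an exchange of names stays open as a hypothesis. The transcript of the deleted gene was not analysed here, and slide and label coincide in series 2. Which series would be exchanged rests only on the known dependence of CDKN1A and other p53 targets on p53. Responses under the KO label at 2 nM are therefore no evidence of a p53 response in cells without p53.

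Untreated arrays numbered 4 and 10 stood apart from the other untreated arrays of their cells under both labels, and KO-labelled replicate 4 lay far from the other 6 untreated KO-labelled arrays for CDKN1A (gap over range 0.737) and p53 targets (0.596), as did WT-labelled replicate 4 for housekeeping genes (0.638). Chance marks about 1 in 20 such groups, and 64 were tested. A slide effect is argued against for WT-labelled arrays 4 and 10 and KO-labelled array 10, which differed from arrays of their own label and slide at least 2.551 times as much as those did among themselves. The slide of KO-labelled array 4 held no other untreated KO-labelled array. Slide as the whole cause is argued against there by r = 0.761 between its difference from arrays 5 and 6 and that of WT-labelled array 4, which shares a slide with its arrays 5 and 6, and a part due to slide stays open. Leptomycin B treated cells named as untreated are argued against by slopes on the drug response of -0.006 at most. A culture set shared by arrays 4 and 10 stays open, because their deviations had r of 0.198 and 0.240 as labelled but also 0.226 and 0.311 across labels. Over whole profiles each of the 4 arrays was most like one of the other label and series, WT 4 and KO 10 with r = 0.991 and KO 4 and WT 10 with 0.992, against at most 0.974 to 0.989 with arrays of its own label and series. Such matches are what a shared set with exchanged names would give, but they were seen before this was weighed and settle neither. No biological explanation was tested.

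Counting the real split, a share under 0.05 of splits called as many genes for the WT and KO responses to 2 nM (1 of 35 splits each, the smallest share possible, 4742 and 5646 genes against at most 3113 and 4107). The share was also under 0.05 for the KO dose difference (3 of 100 drawn from 700 possible, 2789 against a highest other of 4207). So small a draw leaves that share uncertain. Since replicates may be technical, such shares do not exclude chance differences between cultures. The highest other splits at 2 nM set the treated arrays and untreated replicate 10 against untreated replicates 7 to 9, so they nearly mirror the real one. For the responses to 20 nM, 10 splits are too few for a share under 0.05, with 5612 and 4831 genes against at most 25 and 15 (1 of 10 splits each). The share was not under 0.05 for the genotype difference of untreated cells (37 of 100, 40 against 2966), the genotype differences of the responses (8 and 9 of 100, 1155 and 1563 against 3745 and 3752) or the WT dose difference (6 of 100, 2538 against 5974). Splits for the differences of responses exchanged treated arrays and untreated arrays separately and were not held to part arrays 4 or arrays 10. They are therefore no model of equal responses. Among untreated splits that part arrays 4 and part arrays 10, as the real one does, the share was not under 0.05 either (17 of 100, 40 against 2731), and the highest exchanged the labels of all 6 untreated series 1 arrays. The count of 40 comes from the model without replicate number as a block. With that block the real split gave 425 genes, and other splits were not run with it. Splits calling several times the real count point to a structure of the samples: the highest at 2 nM exchanged the labels of all 8 untreated series 2 arrays, and the highest for the WT dose difference exchanged the 20 and 2 nM arrays.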

How the results depend on the processing

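The settings without arrays 4 and 10, with only these as controls, with exchanged names and with centring over probes above 50 were chosen after seeing the data; the others were planned. The 4 responses stayed within 1.5 times their counts under all 18 settings other than single arrays left out, except KO 20 nM (16 of 18). Some of these settings could hardly move a count. Arrays already shared a median and nearly a distribution, and centring over probes above 50 shifted arrays by at most 0.011 (log2). Exchanged names of series 2 leave the 20 nM responses as they were. The centring and quantile settings also count among the cases that follow. So does the setting with all probes, which read each list and named gene through the same probe as the main setting. It therefore did not test other probes of these genes. Lists and named genes kept direction and side of the threshold in 2399 and 3561 cases, lost a call in 204 and 62, gained one in 20 and 51, reversed in 14 and 11 and changed direction with no call in either setting in 51 and 29. The untreated genotype difference (40 genes) had 7 genes with floor 1, 75 with floor 50, 9 with the 60th percentile filter, 0 with series as an additive block and 0 with series ignored (limma, with 1417 at an unadjusted p under 0.05 in the main setting), 3 with slide as a random block, 4 with only the arrays compared and 4414 with array weights. It had 3509 without arrays 4 and 10, 325 with only these and 2731 with exchanged names. KO 20 nM had 3164 with only the arrays compared and 7614 with weights. The 20 nM genotype difference (1155) had 612 with slide as a random block, 755 with only the arrays compared, 5015 with weights, 4366 without arrays 4 and 10 and 2254 with only these. The 2 nM difference (1563) had 4083 with weights, 3965 without arrays 4 and 10 and 2695 with only these. The WT dose difference (2538) had 6157 with weights, 5755 without arrays 4 and 10 and 1124 with exchanged names, and the KO one (2789) 1713 with slide as a random block, 6650, 6226 and 843. The cause was not tested. With replicate number as a block the untreated count was 425. Among treated arrays, and untreated ones other than 4 and 10, the numbers do not pair (r of 0.04 to 0.10 at 20 nM, -0.04 to -0.03 at 2 nM and 0.006 to 0.068 untreated), and the block gave 2883 genes at 20 nM and 3026 at 2 nM.

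Directions that reversed, by sign for genes and by camera for lists, follow; list values are medians, some near 0 or of unchanged sign. With floor 50 the histone median of the WT dose difference was 0. With series as an additive block ADGRF1 was at 1.786 (20 nM genotype difference), -0.217 (2 nM) and -0.566 (KO dose), and RGS2 at -0.421 (2 nM). With series ignored ADGRF1 was at 1.786, -0.217 and -0.775 and RGS2 at -0.421, and in the WT dose difference the export machinery was at -0.429, heat shock genes at -0.193, TFEB genes at 0.005 and CDKN1A at 3.828. With only arrays 4 and 10 as controls the untreated difference had G2/M genes at -0.007, ATF4 genes at 0 and interferon genes at -0.018. In that setting ATF4 genes were at -0.016 (WT 20 nM), 0.134 (20 nM genotype difference) and 0.087 (WT dose), and CDKN1A at 0.417 (KO 20 nM) and 1.469 (WT dose). Export machinery was at -0.217 and hypoxia genes at -0.008 (WT dose), and ribosome biogenesis at -0.099 and hypoxia genes at 0.189 (KO dose).

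Leaving out single arrays gave 17 to 1477 genes for the untreated difference, 5080 to 5653 for WT 20 nM, 4041 to 4646 for WT 2 nM, 4161 to 5561 for KO 20 nM, 5065 to 5680 for KO 2 nM, 834 to 2602 and 1290 to 1826 for the genotype differences at 20 and 2 nM, and 1899 to 3386 and 1940 to 4423 for the WT and KO dose differences. Planned median centring moved nothing. Low signal over background limits dim lists such as the fibroblast markers (median intensity 10.3).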

Other observations

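The tests on arrays 4 and 10, on cycling cells and on bright histone genes were chosen only after the result was seen; that on normalization or floor was written before.

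Untreated arrays of the same label and series were not alike. YAP targets, genes of the Hippo pathway's transcriptional output, were at -0.95 and -0.82 on WT-labelled arrays 4 and 10 and at -1.25 and -0.70 on KO-labelled arrays 4 and 10, against the other untreated arrays of the same cell. CCN2, a matricellular YAP target, was at -3.52, -1.51, -5.32 and -1.06 on these arrays, thrombospondin THBS1 at -2.29, -1.69, -2.46 and -1.69, tissue factor F3 at -2.63, -2.44, -2.34 and -2.42 and the carboxypeptidase CPA4 at -3.28, -2.43, -3.25 and -3.67. CTHRC1, a secreted collagen-associated protein, was at 2.20, 1.52, 2.77 and 1.73. The transcription factor ATF3 was at -4.10 and -3.90 on arrays 4 and at -0.15 and -0.81 on arrays 10, and hypoxia genes at -1.26 and -1.17 against 0.09 and 0.17. Ribosome biogenesis genes were lower on arrays 10, at -0.59 and -0.64. In a model of both labels together, the mean difference of arrays 4 and 10 from the other untreated arrays of their cells was called in 3136 higher and 2851 lower genes (16 residual degrees of freedom). YAP targets passed camera on arrays 4 and on arrays 10 (adjusted p = 1.4e-06 and 8.5e-07, and 0.0163 and 0.0081 with an estimated correlation). Hypoxia genes passed on arrays 4 (6.7e-11, and 7.5e-04 with an estimated correlation) and not on arrays 10 (0.228), and ribosome biogenesis genes on arrays 10 (3.8e-20 and 0.00123) and not on arrays 4 (0.297). The nuclear export and import machinery was at -0.299 on arrays 10 (camera adjusted p = 3.7e-07, and 0.0081 with an estimated correlation). It did not pass on arrays 4 (0.482). The p53 targets were at -0.712 on arrays 4 (camera adjusted p = 1.7e-08, and 0.275 with an estimated correlation). They did not pass on arrays 10 (0.736). On arrays 10 cholesterol synthesis genes were at 0.36 (camera adjusted p = 0.018) and oxidative phosphorylation genes at 0.178 (0.00122). Neither list passed with an estimated correlation (0.491 and 0.0648), and neither passed on arrays 4 (0.64 and 0.101). ATF3 was called on arrays 4 and on arrays 10 (-4.00 ± 0.11 and -0.48 ± 0.11). These arrays and genes were chosen after their values were seen, so the p-values overstate the evidence.

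Histone transcripts were higher in all 4 responses, with list medians of 1.54 to 1.82. A change in the share of cycling cells stays open. In KO-labelled cells at 20 nM, where the histone median was 1.535, 7 G2/M genes rose and 8 fell, and 18 of 41 G1/S genes fell and 7 rose, so these lists do not show an unchanged cell cycle there. With a floor of 50 the median fell to 0.091 in that response, which had been predicted for an effect of normalization or floor. A higher floor can only shrink the changes of dim members, so this fall was fixed in advance and decides nothing. A floor effect is argued against for the 6 members with a mean above 50 in each untreated group, which a floor of 10 does not reach: 4 rose, and their median was at least 1.557 as reported and 1.325 with an offset of 50. The authors' normalization is already in the values and stays open. Replication-dependent histone transcripts mostly lack poly(A) tails and this amplification primes on poly(A), so a change in their tailing stays open and was not tested. Not every member rose: H4C3 was at -0.80, -0.49, -0.30 and -0.83 for WT 20 nM, WT 2 nM, KO 20 nM and KO 2 nM, H2AZ1 at -0.295, 0.015, 0.003 and -0.264, and H2BC7 and H1-4 at 0 in KO-labelled cells at both doses.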
